A study of Mus musculus with 14 samples.

How the data were processed

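Total RNA from snap-frozen liver or liver tumour tissue of 14 samples was isolated with a Qiagen RNeasy kit and made into libraries with the Illumina TruSeq RNA kit v2, per the labels' protocols. This kit does not mark strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The submitters' processing notes name Salmon 0.3.1, edgeR 3.14.0 and the mouse genome build mm9, with no role or order for the tools. The transcript annotation, read length and any trimming are not given in the sources used here.

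The deposited values are estimated counts (expected counts, not whole numbers) for 35230 RefSeq transcript rows in 14 samples, per the file headers. The table has 1 further column, which holds no values and was not used. In each library most low values are whole multiples of one step. Dividing by the step, 1.093 to 1.152 in the 14 libraries, makes 59.8% to 68.0% of the values from 0.5 to 20 whole within 0.01, so 1 read counted for slightly more than 1. Transcript identifiers were matched to gene symbols through a RefSeq table of the assembly GRCm38.p6 (26077 rows) or, for 148 further rows, GENCODE M21, and 9005 rows had no match. Those tables are of another build than the submitters', so they were used for names, transcript length and GC content only and no coordinates are given. Estimated counts were summed per gene and rounded to whole numbers, which gave 30436 features, 21431 of them with a gene name. Unmatched rows were kept as features of their own and took 3.52% to 12.1% of a library. Genes with near-identical copies, such as the Mup, Akr1c, Cyp2b, Cyp3a41, Cyp4a12 and Serpina1 families and the pseudogene Serpina4-ps1, are uncertain, since estimated counts can be split between copies.

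Groups and replicate numbers came from the sample titles and treatments from the labels. The tests, the covariates, the gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, limma 3.58.1) with robust dispersion estimates, TMM normalization and edgeR's filterByExpr, which left 12300 features. All 14 samples entered one fit with 3 groups, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The tumour effect is the mean of the Grow and Regress effects. TMZ was tested as a coefficient beside the group, and SAHA as Grow with SAHA against Grow without, in a fit with 4 groups. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to a common size of the TMM-adjusted library, as the cpm function of edgeR gives them, and log2 CPM was taken with a prior count of 2. The biological coefficient of variation was 0.484.

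The lists, 24 of cell programmes and 13 of cell types with 531 genes in all, came from textbook knowledge. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry as alternatives. Of 33 lists with at least 3 tested genes, camera called 16, 17, 16, 4, 12 and 15 in the 6 comparisons, in the order Tumour, Grow and Regress against Normal, Regress against Grow, TMZ and SAHA. With an estimated correlation it called 0 in each, the lowest adjusted p being 0.158. With fry, adjusted p in Tumour against Normal was 0.0305 for proliferation, oncofetal, MAPK/ERK and cholesterol genes. It was 0.0392 for immediate early genes, 0.0394 for recruited monocytes and 0.0462 for bile acid genes. In Grow against Normal fry gave 0.00642 for proliferation, 0.0221 for MAPK/ERK and 0.0246 for oncofetal genes. In Regress against Normal its lowest adjusted p was 0.0562. H19, Ighm, Igkc, Cd68, Ly6g and Ahsp were list members with no measured row. For each group comparison, the genes named were the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 and non-overlapping values, up to 4 called members of each list with at least 3 called, and in all cases Afp, Gpc3, Glul, Mki67, Cdkn1a and Mgmt. For the treatments they were Cdkn1a, Mgmt, Mki67 and up to 5 genes each way. Features with no symbol and predicted genes were left out. Other genes named were chosen after their values were seen, list members among them.

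The code was tested on simulated counts with the real means, library sizes and dispersions, in which 200 genes were changed. For Grow against Normal (12124 genes) edgeR recovered 15.2%, 67.2% and 90.6% of genes changed by 1, 2 and 4 on the log2 scale, for Regress against Normal (12143 genes) 4.55%, 44.6% and 81.8%, and for Regress against Grow (12130 genes) 7.58%, 64.2% and 87.9%. The share of false calls was 3.42%, 2.27% and 5.36% with edgeR, against 17.5% to 19.1% with DESeq2 and 2.41% to 3.13% with limma-voom. A raised list of 30 genes gave a camera p of 2.09e-31 at the preset and 1.13e-07 at an estimated correlation in a Grow against Normal simulation of 12123 genes, and an unchanged list 0.217 and 0.232. The simulated genes were drawn independently, with no trend on transcript length, no correlation between genes and no libraries close to copies. The simulations thus test the code and do not give the share of false calls in the real data.

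Counts of Grow 3 and Grow 4 differed by more than sampling noise over genes with at least 20 counts per pair, though by less than any other pair, so they stayed 2 samples and were also summed into 1 as an alternative. Alternatives fixed before the data were examined were other scalings and filters, DESeq2 1.42.0, limma-voom, no robust estimates, only the groups compared, the replicate number as a block, treatment covariates, vehicle-treated tumours only, no samples with the shared code, and each sample left out in turn. Alternatives chosen after seeing the data corrected for transcript length and GC content, summed Grow 3 and Grow 4, left out 3 libraries together, divided by the step, dropped unnamed features and Rn28s1, kept transcripts apart, or used clock genes as a covariate. The length trend was a smooth curve per library on log2 transcript length, over the 92.0% of tested genes with a length. No sample was left out of the main fits.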

Results

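Gene expression was measured by RNA sequencing in liver tissue of 14 samples from male C3HeB/FeJ mice, an inbred strain that develops liver tumours spontaneously with age. The labels give 4 samples of normal liver (Normal 1 to 4), 6 of tumours marked Grow (Grow 1 to 6) and 4 of tumours marked Regress (Regress 1 to 4), and do not define how growth or regression was scored. Animals were examined for tumours at 10 months, received 6 cycles of injections on 5 days in every 28, and were 18 months old in the labels. The normal livers received phosphate citrate buffer. Among the Grow tumours, 1 and 5 received the solvent DMSO, 2, 3 and 4 received SAHA (suberoylanilide hydroxamic acid, an inhibitor of histone deacetylases) with TMZ (temozolomide, a drug that alkylates DNA), and 6 received SAHA alone. Among the Regress tumours, 1 and 3 received TMZ, 2 received buffer and 4 received DMSO. Regress 2 was thus the only tumour labelled with buffer alone, so tumour effects cannot be fully separated from those of the solvent or drug. TMZ was given at 31 mg/kg alone and 22 mg/kg with SAHA, and SAHA at 100 mg/kg alone and 85 mg/kg with TMZ. Library totals, in M (mega) estimated counts, were 5.27, 5.94, 6.43 and 7.47 in Normal 1 to 4, 13.39, 5.90, 6.24, 7.11, 9.30 and 5.99 in Grow 1 to 6, and 6.17, 6.09, 4.71 and 5.96 in Regress 1 to 4. Normal 4 and Regress 2 carry the same sample code. Codes differ within each group, but the labels do not say what a code identifies, so the p-values measure the spread between these samples only.

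The comparison of all tumours with normal liver addresses how spontaneous hepatocellular carcinoma differs from normal tissue. Cyclin D1 (Ccnd1), which drives entry into the cell cycle, stood at 4.49 ± 0.949 CPM (counts scaled to library size, SD, n = 4) in normal liver, 41.0 ± 6.45 in Grow (n = 6) and 32.4 ± 18.8 in Regress (n = 4). Every tumour library lay above every normal library. Dusp6, the ERK phosphatase induced by ERK signalling, stood at 19.7 ± 1.95, 94.8 ± 20.1 and 86.8 ± 39.1 CPM in the same order. The fetal liver protein Afp was at 1.77 ± 1.88, 112 ± 99.7 and 179 ± 192 CPM, and the mitotic kinase Cdk1 at 0.542 ± 0.294, 6.28 ± 1.79 and 4.67 ± 3.00 CPM. Bmf, a BH3-only promoter of cell death, went the other way, from 19.6 ± 7.79 to 2.15 ± 1.55 and 3.81 ± 1.01 CPM. In all, 285 of 12300 tested genes were called at an adjusted p under 0.05 by edgeR, 195 higher and 90 lower in tumours, of which 271 differed by at least 1 on the log2 scale. The largest rises with non-overlapping values were in Ly6d (log2 fold change 7.37 ± 1.33 SE, adjusted p = 0.0221), the trefoil peptide Tff3 (6.15 ± 1.24) and the fatty acid elongase Elovl7 (6.04 ± 1.23). They were followed by the insulin-like growth factor binding protein Igfbp1 (5.12 ± 1.04), the metalloprotease Mep1b (4.91 ± 0.96) and the immediate early transcription factor Egr1 (4.63 ± 0.94). All but Ly6d had an adjusted p of 0.0290. The largest falls were in Usp2 (-3.53 ± 0.71) and Noct (-2.96 ± 0.59), both with a daily rhythm in liver. They were also in the uridine phosphorylase Upp2 (-3.40 ± 0.81, adjusted p = 0.0434), Gna14 (-2.91 ± 0.71, adjusted p = 0.0481), the actin regulator Cyfip2 (-2.80 ± 0.54) and Bmf (-2.76 ± 0.41, adjusted p = 0.0120), with 0.0290 for Usp2, Noct and Cyfip2. Among clock genes, Hlf (-1.56 ± 0.24, adjusted p = 0.0168) and Per2 (-1.73 ± 0.42, adjusted p = 0.0460), both chosen after their values were seen, were called lower in tumours, while Arntl (3.50 ± 0.89, adjusted p = 0.0539) and Dbp (-1.72 ± 0.90, adjusted p = 0.346) did not pass. A log2 ratio of Arntl and Npas2 to Dbp and Per3 averaged -5.97 in Normal, 0.04 in Grow and -0.20 in Regress, and with it as a covariate 326 genes were called, 127 of them among the 285. The ratio ran from -6.70 to -4.69 in Normal and from -2.54 to 3.93 in all tumours but Regress 2 (-5.92). It thus largely followed the groups, so this fit cannot separate the clock from the tumour effect.

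Among the gene lists, proliferation genes lay higher in tumours. Of 29 tested, 12 were called higher and none lower, and 25 were higher adjusted over the list alone, with a median log2 fold change of 3.31. Cdk1 (3.31 ± 0.52, adjusted p = 0.0173), Bub1b (3.70 ± 0.72), Ccnb2 (3.76 ± 0.76) and Ccna2 (3.88 ± 0.78, these 3 at adjusted p = 0.0290) were among them, while Mki67 stood at 3.94 ± 1.11 with an adjusted p of 0.0722. The list passed camera (adjusted p = 8.79e-22), with adjusted p = 0.184 with an estimated correlation. Of the 12 tested oncofetal and liver tumour markers, 6 rose and 10 did so adjusted over the list alone (median 5.50, camera adjusted p = 9.54e-12, adjusted p = 0.184 with an estimated correlation). They included Afp (6.29 ± 1.36, adjusted p = 0.0328), the proteoglycan Gpc3 (6.26 ± 1.51, adjusted p = 0.0457) and Akr1c18, a steroid-metabolising reductase of a family with near-identical members (7.91 ± 1.46, adjusted p = 0.0236). Of 13 MAPK/ERK output genes, which follow ERK activity, 4 rose and 11 did so adjusted over the list alone (median 1.34, camera adjusted p = 7.5e-11, adjusted p = 0.184 with an estimated correlation). The called genes were Ccnd1 (3.02 ± 0.37) and Dusp6 (2.20 ± 0.30), both at adjusted p = 0.0109, Spred1 (1.12 ± 0.26, adjusted p = 0.0397) and Dusp5 (6.58 ± 1.60, adjusted p = 0.0465). Of 19 genes of fatty acid oxidation and PPARa targets, 4 rose in both counts and 1 fell adjusted over the list alone. These were the pantetheinase Vnn1 (4.78 ± 0.86, adjusted p = 0.0221), the pyruvate dehydrogenase kinase Pdk4 (2.97 ± 0.60, adjusted p = 0.0290), the hormone Fgf21 (2.42 ± 0.53, adjusted p = 0.0348) and the lipid droplet protein Plin2 (1.90 ± 0.44, adjusted p = 0.0403). None of these is an enzyme of the oxidation pathway itself. The list's median of -0.16 and mean of 0.42 had opposite signs (camera adjusted p = 0.562, toward higher). The cell cycle inhibitor Cdkn1a rose (2.80 ± 0.63, adjusted p = 0.0374), whereas glutamine synthetase (Glul, 1.78 ± 1.53, adjusted p = 0.650) and the alkylation repair enzyme Mgmt (-0.04 ± 0.39, adjusted p = 0.982) did not pass. At least 1 normal library had no count for Elovl7, Bub1b, Ccnb2, Akr1c18 and Dusp5, so their folds rest on low counts.

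Cholesterol synthesis genes lay higher in tumours (2 of 21 called, 7 adjusted over the list alone, median 0.73, camera adjusted p = 3.66e-09, adjusted p = 0.231 with an estimated correlation), led by Mvd (1.58) and Hmgcs1 (2.01). The 17 genes of bile acid synthesis and transport lay lower, with 1 called and 3 adjusted over the list alone (median -0.97, camera adjusted p = 5.83e-07, adjusted p = 0.261 with an estimated correlation). The called gene was the bile acid uptake transporter Slc10a1 (-1.66, adjusted p = 0.0369). Of 18 periportal genes 1 fell, the urea cycle enzyme Asl (-1.43 ± 0.27, adjusted p = 0.0238), and 3 fell and 1 rose adjusted over the list alone (median -0.80, camera adjusted p = 1.44e-04, adjusted p = 0.468 with an estimated correlation). Immediate early genes had 2 of 9 called higher, Egr1 and Jun, and 6 adjusted over the list alone (median 1.32, camera adjusted p = 1.00e-05, adjusted p = 0.231 with an estimated correlation). Among p53 targets, Cdkn1a and Btg2 were called of 18, and 3 adjusted over the list alone (median 0.51, camera adjusted p = 0.00591, adjusted p = 0.468 with an estimated correlation). The 13 male-biased liver genes had none called and 1 lower adjusted over the list alone (median -1.49, camera adjusted p = 4.88e-04). The 8 female-biased genes had 1 called higher, Cyp2b13 of the closely related Cyp2b family, with 4 higher and 2 lower adjusted over the list alone (median 1.06, camera adjusted p = 0.0222). Both had adjusted p = 0.468 with an estimated correlation. Beside these sex-biased lists, the male-biased gene Hsd3b5 stood at 5.43 CPM in Normal 2 against 92.2 to 337 in the other normal livers. MHC genes had none of 13 called (median 0.50, camera adjusted p = 0.0491, adjusted p = 0.553 with an estimated correlation).

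For markers of other cell types few single genes were called, and camera called 5 of the lists only at its fixed correlation. Recruited monocyte and macrophage markers had none of 9 called and 3 higher adjusted over the list alone (median 0.99, camera adjusted p = 1.70e-04, adjusted p = 0.231 with an estimated correlation). Kupffer cell markers had none of 12 called and 1 lower adjusted over the list alone (median -0.70, camera adjusted p = 0.00522, adjusted p = 0.507 with an estimated correlation). Their mean was 6.02 log2 CPM in Normal 1 against 4.29 to 4.58 in Normal 2 to 4. It was 2.13 in Grow 1 against 3.43 to 5.04 in the other tumours. For continuous endothelium 1 of 8 was called higher, Cd34, and 4 adjusted over the list alone (median 1.04, camera adjusted p = 0.00522, adjusted p = 0.468 with an estimated correlation). Stellate cell and matrix genes had 1 of 14 called higher, Tagln, with 7 higher and 2 lower adjusted over the list alone (median 1.58, camera adjusted p = 0.0222, adjusted p = 0.553 with an estimated correlation). Regress 4 held 186 CPM of the collagen gene Col1a1 against at most 9.59 in any other library. Cholangiocyte and ductular genes had 1 of 7 called higher, Tspan8, and 2 adjusted over the list alone (median 2.49, camera adjusted p = 0.00326, adjusted p = 0.231 with an estimated correlation). Both tested adipocyte markers, Fabp4 and Cidec, rose. Camera made no call for the imprinted gene network (adjusted p = 0.0900), hepatocyte identity (0.288, Tat called lower), Wnt/beta-catenin and pericentral genes (0.562, median 0.48 and mean 0.65 but camera toward lower), lipogenesis (0.0612, Dgat2 called lower), or glycolysis (0.0771). It made none either for repair of alkylated DNA and mismatches (0.649), histone deacetylases (0.576), NRF2 targets (0.808, Srxn1 called higher), unfolded protein and amino acid stress (0.0618) or acute phase (0.264, Orm3 called lower). Among the rest, it did not call interferon response (0.111), NK and cytotoxic cells (0.562), B cells and plasma cells (0.0912), neutrophils (0.808), liver sinusoidal endothelium (0.808, Lyve1 called higher) or erythroid cells (0.0618). T cells and immune checkpoints had 2 tested genes each and pancreatic acinar cells 1, none of them called, too few for camera.

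The count of 285 depended on the libraries in the fit. Regress 1 lay close to normal liver, with Afp at 0.591 CPM, and without it 991 genes were called, including all 285. Grow 3 and Grow 4 were close to copies of each other, and summing them into 1 sample, a setting chosen after seeing the data, left 216 calls, 207 of them among the 285. In another setting chosen after seeing the data, removing each library's trend of expression on transcript length, which differed between libraries, gave 646 calls (447 higher and 199 lower, and 24 to 1425 calls with 1 library left out) among genes with a known length, including 268 of the 280 main calls tested there. Under that correction 19 proliferation genes, 8 oncofetal markers, 6 MAPK/ERK output genes and 4 genes of the fatty acid oxidation list were called higher. Without Normal 4 and Regress 2, which share a code, edgeR called 0 genes (1493 at an unadjusted p under 0.05). The count was 8, 58, 0 and 14 without Normal 1, 2, 3 and 4 (1752 genes at an unadjusted p under 0.05 without Normal 3), 161, 119 and 98 without Grow 1, 5 and 6, and 118 without Regress 3. With other tools it was 1055 (DESeq2) and 127 (limma-voom, 45 higher and 82 lower, so the balance of directions turned).

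**Figure D1:**
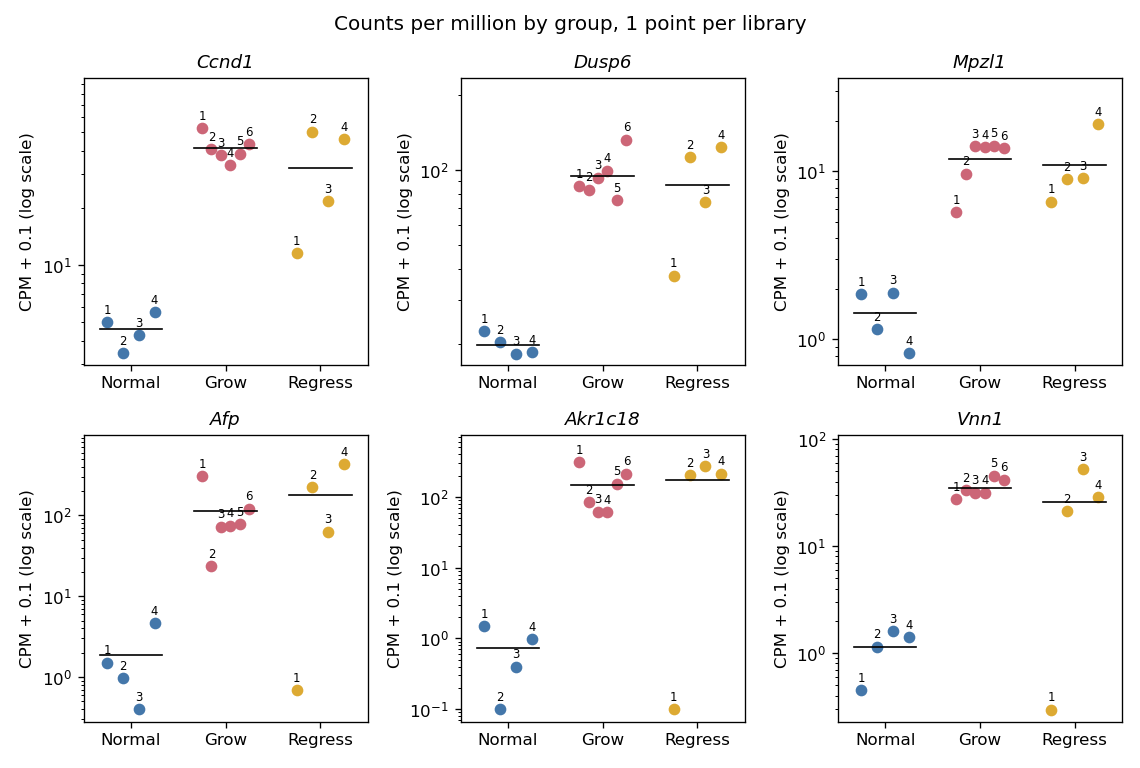
Expression of Ccnd1, Dusp6, Mpzl1, Afp, Akr1c18 and Vnn1 in CPM plus 0.1 on a log axis, 1 point per library labelled with its replicate number, with a black line at each group's arithmetic mean. Ccnd1 ranges from 3.33 to 5.53 CPM in Normal and from 11.4 to 52.4 CPM in the tumours, where Regress 1 is the lowest library.

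The comparison of Grow tumours with normal liver addresses what set the tumours marked Grow apart from normal tissue. No Grow tumour was labelled with buffer alone, as the normal livers were, so tissue and injected solvent or drug cannot be separated here. The genes with the largest rises were Alox5, which makes leukotrienes (log2 fold change 7.83 ± 1.77 SE, adjusted p = 0.0423), Akr1c18 (7.80 ± 1.47, adjusted p = 0.0280) and Cyp2b13 (7.66 ± 1.28, adjusted p = 0.0183). Next came Erich4 (7.44 ± 1.71, adjusted p = 0.0424), Ly6d (7.43 ± 1.35, adjusted p = 0.0261) and the adaptor protein gene Shc2 (6.71 ± 1.28, adjusted p = 0.0287). Akr1c18 rose from 0.644 ± 0.623 CPM in normal liver (SD, n = 4) to 147 ± 99.4 CPM (n = 6), and Ly6d from 0.491 ± 0.263 to 86.4 ± 104 CPM. The largest falls were in the pseudogene Serpina4-ps1 (-5.97 ± 1.29), Upp2 (-4.69 ± 1.00), Plekhb1 (-4.00 ± 0.82), the carboxylesterase Ces1e (-3.35 ± 0.78), Ankrd55 (-3.31 ± 0.61) and Bmf (-3.18 ± 0.48), with adjusted p from 0.0129 to 0.0436. Upp2 fell from 559 ± 214 to 21.6 ± 16.5 CPM. edgeR called 217 of 12300 genes, 138 higher and 79 lower, of which 214 differed by at least 1 on the log2 scale. Reads of Akr1c18, Cyp2b13 and Serpina4-ps1 may be shared with closely related genes, and at least 1 normal library had no count for Alox5, Cyp2b13, Erich4 and Shc2.

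Proliferation genes rose in Grow tumours, 14 of 29 over all genes and 25 adjusted over the list alone (median 3.52, camera adjusted p = 4.35e-27, adjusted p = 0.158 with an estimated correlation). They included Cdk1 (3.52, adjusted p = 0.0130), Bub1b (4.06, adjusted p = 0.0261), and Ccnb2 (4.06) and Ccna2 (4.16), both at adjusted p = 0.0287, while Mki67 stood at 4.29 ± 1.15 with an adjusted p of 0.0675. Of 12 oncofetal markers 4 rose and 10 did so adjusted over the list alone (median 5.09, camera adjusted p = 2.60e-12, adjusted p = 0.158 with an estimated correlation). Tff3 (5.44, adjusted p = 0.0404) and Afp (5.96, adjusted p = 0.0424) were among them, and Gpc3 missed the threshold (6.37 ± 1.54, adjusted p = 0.0503). Ccnd1 (3.19 ± 0.39, adjusted p = 0.00508), Dusp6 (2.26 ± 0.31, adjusted p = 0.00874) and Spred1 (1.25, adjusted p = 0.0384) rose. These are 3 of the 13 MAPK/ERK output genes, and 12 rose adjusted over the list alone (median 1.52, camera adjusted p = 3.22e-11, adjusted p = 0.158 with an estimated correlation). Vnn1 (5.01, adjusted p = 0.0239), Fgf21 (2.80, adjusted p = 0.0287) and Pdk4 (3.07, adjusted p = 0.0301) rose within the fatty acid oxidation list, which camera did not call (adjusted p = 0.185). Periportal genes lay lower (1 of 18 called, Asl at -1.83 ± 0.30, with 4 lower and 1 higher adjusted over the list alone, median -1.01, camera adjusted p = 4.26e-06, adjusted p = 0.381 with an estimated correlation). Their mean log2 CPM was 5.28 in Grow 3 and 5.36 in Grow 4, against 7.32 to 8.15 in the other Grow tumours and 7.75 to 8.45 in normal liver. Bile acid genes lay lower too, with Slc10a1 and the bile acid receptor Nr1h4 called of 17 (median -1.25, camera adjusted p = 4.26e-06, adjusted p = 0.357 with an estimated correlation). So did acute phase genes, with 1 of 17 called and 4 lower and 1 higher adjusted over the list alone (median -0.33, camera adjusted p = 0.0107, adjusted p = 0.404 with an estimated correlation). Among markers of other cell types, none was called over all genes in 4 lists that camera called. Continuous endothelium had 5 of 8 higher adjusted over the list alone (median 1.22, camera adjusted p = 9.73e-04, adjusted p = 0.357 with an estimated correlation). Cholangiocyte and ductular genes had 1 of 7 higher (median 1.25, camera adjusted p = 0.0129, adjusted p = 0.357 with an estimated correlation). Recruited monocyte and macrophage markers had none of 9 (median 0.76, camera adjusted p = 0.00693, adjusted p = 0.381 with an estimated correlation), and Kupffer cell markers 2 of 12 lower (median -0.80, camera adjusted p = 0.00274, adjusted p = 0.457 with an estimated correlation). The Kupffer list stood apart in Normal 1, which was high, and Grow 1, which was low. Dcn, a matrix proteoglycan chosen after its values were seen, fell (-2.36 ± 0.39, adjusted p = 0.0178), while the stellate cell and matrix list went both ways, with 4 of 14 higher and 3 lower adjusted over the list alone (median 0.89, camera adjusted p = 0.601, toward higher). Cdkn1a (2.56 ± 0.65, adjusted p = 0.0572), Glul (3.18 ± 1.72, adjusted p = 0.394) and Mgmt (-0.46, adjusted p = 0.674) did not pass. The rise of Glul came from Grow 3 and Grow 4 (9962 and 9771 CPM), since the other Grow tumours (31.4 to 159 CPM) lay below every normal liver (225 to 583 CPM), and with vehicle-treated tumours only Glul in Grow vs Normal was at -3.142.

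In settings chosen after seeing the data, 113 genes were called with Grow 3 and Grow 4 summed, 107 of them among the 217, and 529 (350 higher, 179 lower, and 39 to 498 with 1 library left out) with the length trend removed. With the clock ratio as a covariate, which did not overlap between Grow and Normal, the count was 79, of which 45 were among the 217. In settings fixed beforehand, the count was 319 with both drugs as covariates and 488 with vehicle-treated tumours only (in Grow, the DMSO tumours Grow 1 and 5), and 116 of the 217 were called in each. It was 18 without the 2 samples that share a code. The count was 4, 24, 12 and 6 without Normal 1, 2, 3 and 4 and 37, 140, 135, 54 and 25 without Grow 1, 3, 4, 5 and 6, and only 1 proliferation gene was called without Normal 2. It was 1014 with DESeq2, 90 with limma-voom (32 higher and 58 lower, again the other balance) and 877 in a fit of these 2 groups alone.

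The comparison of Regress tumours with normal liver called 3 genes, all higher. The first was Mpzl1, a cell surface glycoprotein that binds a tyrosine phosphatase (log2 fold change 3.02 ± 0.44 SE, adjusted p = 0.0388). The others were Ccnd1 (2.85 ± 0.40, adjusted p = 0.0388) and Dusp6 (2.14 ± 0.33, adjusted p = 0.0457). Each of the 3 was higher in 4 of 4 Regress libraries than in any normal library. Mpzl1 stood at 10.9 ± 5.58 CPM (SD, n = 4) against 1.33 ± 0.528 (n = 4). Of the other genes followed, Afp (6.63 ± 1.42, adjusted p = 0.0569), Cdkn1a (3.04 ± 0.69, adjusted p = 0.0621), and Gpc3 (6.15 ± 1.56, adjusted p = 0.0790) did not pass. Neither did Mki67 (3.58 ± 1.18, adjusted p = 0.153), Mgmt (0.37 ± 0.46, adjusted p = 0.726) or Glul (0.39 ± 1.65, adjusted p = 0.926). By list, no proliferation gene and no oncofetal marker was called over all genes. Adjusted over the list alone, 22 of 29 and 11 of 12 were higher (medians 3.09 and 5.57, camera adjusted p = 8.83e-14 and 1.69e-09, both with adjusted p = 0.226 with an estimated correlation). MAPK/ERK output genes had Ccnd1 and Dusp6 called, and 7 of 13 higher adjusted over the list alone (median 1.17, camera adjusted p = 1.53e-08, adjusted p = 0.226 with an estimated correlation). Stellate cell and matrix genes had 9 of 14 higher and 1 lower adjusted over the list alone (median 2.00, camera adjusted p = 1.26e-04, adjusted p = 0.474 with an estimated correlation), beside the high collagen levels of Regress 4. Recruited monocyte and macrophage markers had 4 of 9 higher adjusted over the list alone (median 1.19, camera adjusted p = 2.94e-05), and cholangiocyte and ductular genes 4 of 7 (median 3.73, camera adjusted p = 0.00254), both with adjusted p = 0.226 with an estimated correlation. Continuous endothelium had 3 of 8 higher (median 0.85, camera adjusted p = 0.0433), and B cells and plasma cells none of 6 (median 1.10, camera adjusted p = 0.0426), both with adjusted p = 0.589 with an estimated correlation. At an unadjusted p under 0.05, 1988 genes differed.

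The count of 3 followed the libraries in the fit. In settings chosen after seeing the data it was 0 with Grow 3 and Grow 4 summed (1927 genes at an unadjusted p under 0.05). With the length trend removed it was 184 (160 higher, 24 lower, and 0 to 1086 with 1 library left out), with 7 proliferation genes and 5 oncofetal markers called. The same correction still left 336 genes between Normal 2 with Regress 1 to 3 and the other libraries of these groups. The 184 therefore cannot be taken as due to the groups. In a setting fixed beforehand, without Regress 1, in which Ccnd1 was at 11.4 CPM, Dusp6 at 37.4 CPM and Mpzl1 at 6.50 CPM, 667 genes were called, of which 14 were proliferation genes and 9 oncofetal markers. Without Normal 2 none was called by edgeR, nor without Normal 1, Normal 3, Normal 4, Regress 2 or Regress 3 (2312, 1903, 1395, 1583, 1578 and 1515 genes at an unadjusted p under 0.05, in this order), and 13 were called without Regress 4. Without the 2 samples that share a code edgeR called 0 (1175 at an unadjusted p under 0.05). DESeq2 called 712 genes and limma-voom 0.

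The comparison of Regress with Grow tumours asks whether the tumours differ by their course, and it is also the test of whether their differences from normal liver differ. SAHA was given only to Grow tumours and TMZ alone only to Regress tumours, so course and drug cannot be fully separated here. edgeR called none of 12300 genes, with 1230 at an unadjusted p under 0.05, DESeq2 called 31 and limma-voom 0. Stellate cell and matrix genes lay higher in Regress tumours by camera (median 1.78, adjusted p = 2.00e-05, 7 of 14 higher adjusted over the list alone, adjusted p = 0.975 with an estimated correlation). Dcn was at 2.07 ± 0.38 and Lum, a related proteoglycan, at 3.07 ± 0.60. Regress 4 alone held 64.8 CPM of Lum, against at most 20.1 in any other library. Acute phase genes lay higher (median 0.83, camera adjusted p = 0.00147, 3 of 17 higher adjusted over the list alone). Their mean log2 CPM was 8.98, 7.89, 9.11 and 7.89 in Regress 1 to 4, against 7.39 to 8.36 in Grow. The higher values thus lay in Regress 1 and 3, which had TMZ alone. Group means were 8.47 in Regress, 8.56 in normal liver and 7.81 in Grow. The serum amyloid genes Saa1 and Saa2 were at 3.47 ± 0.90 and 3.24 ± 0.83, and Saa1 stood at 755 CPM in Regress 1 against 12.4 to 43.3 in Regress 2 to 4. Proliferation genes lay lower (median -0.51, camera adjusted p = 7.46e-04) and periportal genes higher (median 0.28, camera adjusted p = 0.0375), neither with a member called adjusted over the list alone. These 3 lists also had adjusted p = 0.975 with an estimated correlation. With vehicle-treated tumours only, camera turned the direction of the acute phase and periportal lists. The proliferation list averaged 0.64, 0.38, 1.65 and 2.63 log2 CPM in Regress 1 to 4, against 1.76 to 2.60 in Grow, so the lower values lay mainly in Regress 1 and 2. The periportal mean was at 5.28 and 5.36 log2 CPM in Grow 3 and Grow 4, against 7.32 to 8.15 in the other Grow tumours and 6.65 to 8.17 in Regress. Afp (0.67 ± 0.98, adjusted p = 0.751), Gpc3 (-0.22 ± 1.10, adjusted p = 0.937), and Glul (-2.79 ± 1.69, adjusted p = 0.515) did not pass. The same held for Mki67 (-0.71 ± 0.89, adjusted p = 0.711), Cdkn1a (0.48 ± 0.56, adjusted p = 0.694) and Mgmt (0.83 ± 0.41, adjusted p = 0.491). Without Regress 4 the count was 1249, and without any other single library it was 0. With the length trend removed or Grow 3 and Grow 4 summed, settings chosen after seeing the data, it was 0 as well.

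For TMZ, 5 tumours that received it, alone or with SAHA, were compared with 5 that did not, with the tissue group in the fit. edgeR called no gene (1704 at an unadjusted p under 0.05), DESeq2 called 464 and limma-voom 2. Genes of bile acid synthesis and transport lay higher with TMZ (median 1.37, 10 of 17 adjusted over the list alone, camera adjusted p = 3.95e-12, adjusted p = 0.184 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 5.60 ± 1.26 and the sterol 12-alpha-hydroxylase Cyp8b1 at 4.27 ± 0.96, both at adjusted p = 0.081. Male-biased liver genes lay higher as well (median 3.48, 8 of 13 adjusted over the list alone, camera adjusted p = 2.32e-11, adjusted p = 0.314 with an estimated correlation). Nat8 was at 5.63 ± 1.00, Susd4 at 5.70 ± 1.09 and Cyp7b1 at 3.95 ± 0.78 (adjusted p = 0.067 for each). Wnt/beta-catenin and pericentral genes had a median of 3.17, with 3 of 16 higher adjusted over the list alone (camera adjusted p = 9.04e-08, adjusted p = 0.481 with an estimated correlation). That list averaged 7.83 and 7.79 log2 CPM in Grow 3 and Grow 4, but 3.96, 4.29 and 3.76 in the other TMZ tumours, Grow 2, Regress 1 and Regress 3, and 5.75 in Regress 4 without TMZ. Oncofetal markers lay lower (median -2.08, 7 of 12 adjusted over the list alone, camera adjusted p = 5.41e-07, adjusted p = 0.322 with an estimated correlation). So did p53 targets (median -0.81, 10 of 18 adjusted over the list alone, camera adjusted p = 3.69e-04, adjusted p = 0.481 with an estimated correlation). Markers of other cell types moved by camera too, each with adjusted p = 0.481 with an estimated correlation. Kupffer cell markers (median 0.74, 2 of 12 adjusted over the list alone, camera adjusted p = 3.91e-04), B cells and plasma cells (median 1.18, 2 of 6, camera adjusted p = 0.0274) and erythroid cells (median 0.68, 1 of 4, camera adjusted p = 0.0441) lay higher with TMZ. Continuous endothelium lay lower (median -0.66, none of 8, camera adjusted p = 0.00343). Regress 1, which lay close to normal liver, is 1 of the 5 TMZ tumours. The p53 target Cdkn1a was at -1.25 ± 0.47 (adjusted p = 0.265), Mgmt at 0.50 ± 0.40 (adjusted p = 0.548) and Mki67 at -1.39 ± 0.83 (adjusted p = 0.457). The bile acid list averaged 6.76, 7.24, 7.28, 7.62 and 6.34 log2 CPM in the TMZ tumours Grow 2, 3 and 4 and Regress 1 and 3, against 4.23 to 5.65 in the tumours without TMZ. The male-biased gene Nat8 was less even, and was at 59.8, 56.4 and 25.0 CPM in Grow 3, Grow 4 and Regress 1. It was at 3.41 and 3.61 CPM in the other TMZ tumours, Grow 2 and Regress 3, and at most 1.69 CPM in the tumours without TMZ. The count was 737 without Grow 2, 110 without Regress 3 and 4 without Regress 1. In settings chosen after seeing the data it was 71 (0 to 970 with 1 library left out) with the length trend removed and 0 when Grow 3 and Grow 4 were also summed.

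For SAHA, the 4 Grow tumours that received it were compared with the 2 that did not. edgeR called no gene (325 at an unadjusted p under 0.05), DESeq2 called 52 and limma-voom 0. Wnt/beta-catenin and pericentral genes, which mark hepatocytes near the central vein and tumours with active beta-catenin, had a median of 4.89, with 15 of 16 higher adjusted over the list alone (camera adjusted p = 5.87e-21, adjusted p = 0.196 with an estimated correlation). The list moved with 2 of the 4 libraries. Glul stood at 9962 CPM in Grow 3 and 9771 CPM in Grow 4, against 159 in Grow 2 with the same treatment. It was at 31.4 in Grow 6 with SAHA alone, 39.6 and 43.7 in Grow 1 and 5 with DMSO, and at 225 to 583 in normal liver. The ammonium transporter gene Rhbg followed the same order, with 307 and 279 CPM in Grow 3 and Grow 4. Kupffer cell markers (median 1.38, camera adjusted p = 6.52e-12), bile acid genes (median 1.10, 3.01e-10) and the fatty acid oxidation list (median 0.39, 5.21e-05) also lay higher by camera, each with adjusted p = 0.196 with an estimated correlation. Male-biased genes (median 1.78, camera adjusted p = 1.87e-05), B cells and plasma cells (median 1.41, camera adjusted p = 0.00816) and erythroid cells (median 1.00, camera adjusted p = 0.0277) lay higher too. Oncofetal markers (median -1.37, camera adjusted p = 6.25e-04) and continuous endothelium (median -0.59, camera adjusted p = 0.00432) lay lower. These 5 lists had no member called adjusted over the list alone and adjusted p = 0.414 with an estimated correlation. B cell markers averaged 2.03 and 2.17 log2 CPM in Grow 3 and 4, but 0.60 and 0.35 in Grow 2 and 6. They were at 0.36 and 0.74 in Grow 1 and 5. Grow 6, with SAHA alone, lay between Grow 1 and 5 for male-biased genes (2.18 against 1.43 and 4.11) and oncofetal markers. Bile acid genes were at 5.65 in both Grow 5 and Grow 6. The fatty acid oxidation, Kupffer cell, erythroid, cholangiocyte and continuous endothelium lists set all SAHA tumours apart from Grow 1 and 5. Cholangiocyte and ductular genes lay lower (median -1.28, 1 of 7 adjusted over the list alone, camera adjusted p = 0.00296, adjusted p = 0.253 with an estimated correlation). Grow 1, 1 of the 2 tumours without SAHA, had a Kupffer cell mean of 2.13 log2 CPM, against 3.68 to 4.54 in the other Grow tumours. Cdkn1a (-0.83 ± 0.74), Mgmt (0.36 ± 0.58) and Mki67 (-0.05 ± 1.19) did not pass, each at adjusted p = 1.00. No single library left out gave a call, except 1 gene without Grow 1 when the length trend was removed too, and 3 of the 4 treated tumours also had TMZ.

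**Figure D2:**
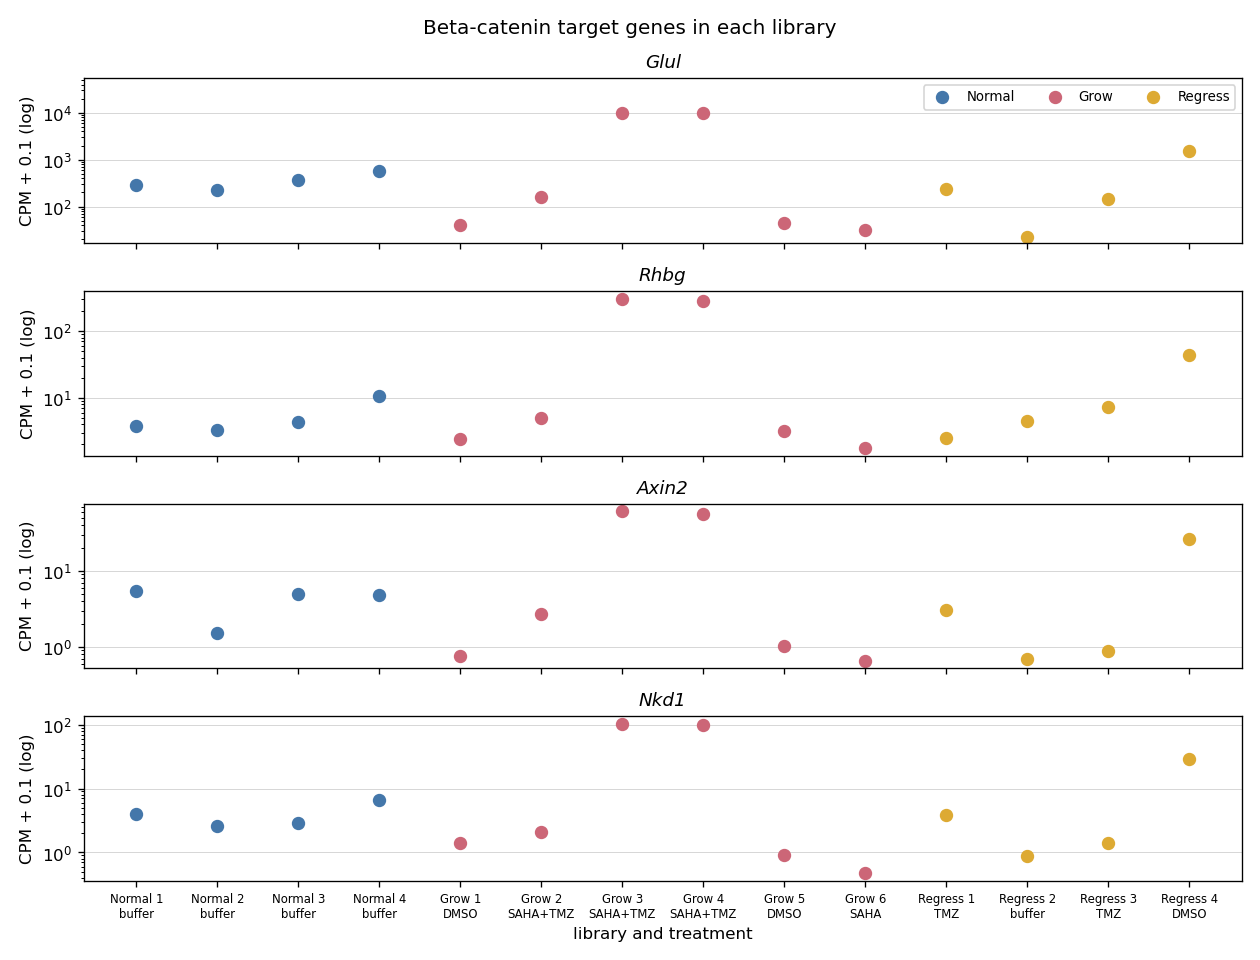
Expression of the beta-catenin targets and pericentral genes Glul, Rhbg, Axin2 and Nkd1 in CPM plus 0.1 on a log axis, 1 point per library with its treatment. Grow 3 and Grow 4 stand apart from the other libraries, with Glul at 9962 and 9771 CPM and Axin2 at 61.4 and 57.1 CPM.

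Grow and Regress tumours were each compared with the same 4 normal livers, and their log2 fold changes across 12300 genes, which are not independent replicates, correlated at 0.791 with a covariance of 0.857. In 20 simulations with no change in either group the mean correlation was 0.552 and the mean covariance 0.160, and the difference of the covariances was 0.697. With the normal livers split so that each group had its own pair, the correlation averaged 0.567 and the covariance 0.674 over the 6 splits. The 3 genes called in Regress, Ccnd1, Dusp6 and Mpzl1, were all among the 138 called higher in Grow, where independent lists would share 0.0337, a value that leaves out the normal livers both lists share. In the 6 splits with separate normal livers edgeR called 0 genes in Regress (542 to 1350 at an unadjusted p under 0.05), so none was shared.

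Length slopes and ribosomal RNA varied within each group, but Regress 1, 2 and 3 had the lowest length slopes of all libraries. The length trend is thus partly tied to the Regress group. The slope of expression on transcript length, in log2 units per doubling of length, was 0.02 ± 0.33 (SD, n = 4) in Normal, 0.13 ± 0.23 (n = 6) in Grow and -0.22 ± 0.42 (n = 4) in Regress. It was 0.48 in Normal 3, 0.44 in Grow 2 and 0.40 in Regress 4 against -0.39, -0.41 and -0.49 in Regress 1, 2 and 3. 28S ribosomal RNA (Rn28s1) took 1.70% to 9.15% of a library. Albumin (Alb), the main secreted protein of hepatocytes, took 2.98% to 4.95% of normal libraries and 9.25% to 17.6% of 7 tumour libraries. The other 3, Grow 3, Grow 4 and Regress 1, had 3.30%, 3.16% and 4.18%.

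**Figure D3:**
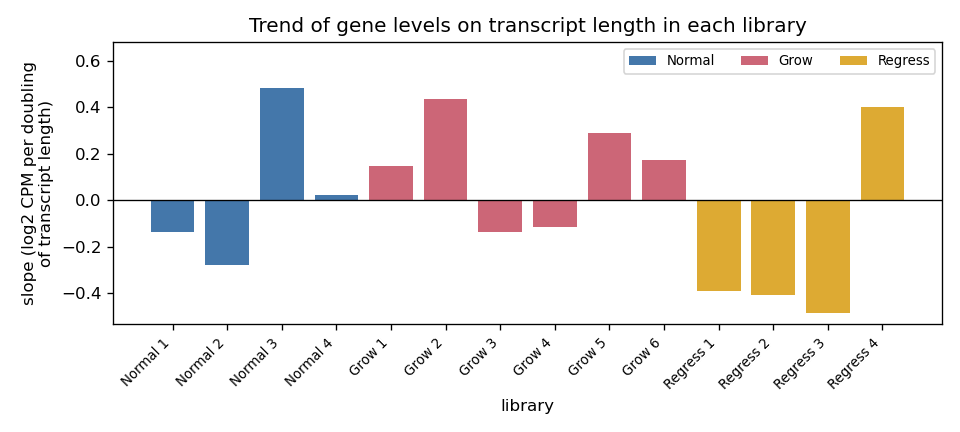
Slope of expression on transcript length in each library, in log2 units per doubling of length, as bars from 0 grouped by Normal, Grow and Regress. The slopes run from -0.49 in Regress 3 to 0.48 in Normal 3, and each group holds libraries on both sides of 0.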

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

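In this part, the tests on Grow 3 and Grow 4, on Regress 1 and of other splits of the samples were chosen only after the result was seen. Of 237 groups of values checked, 18 values stood apart from the rest of their group, several of them in the same library, where chance at 1 in 20 gives 11.85. Regress 1 had no count of Akr1c18, Alox5, Erich4 and Shc2, which is -1.79 in log2 CPM, against 7.67 to 8.07, 5.19 to 5.65, 3.63 to 4.35 and 3.88 to 4.74 in Regress 2 to 4. Its unfolded protein and amino acid stress genes averaged 4.91 in log2 CPM against 5.71 to 5.87, and in Normal 1 the same list averaged 5.57 against 5.08 to 5.15 in the other normal livers. Kupffer cell and macrophage markers averaged 6.02 in Normal 1 against 4.29 to 4.58 in Normal 2 to 4, and 2.13 in Grow 1 against 3.68 to 4.54 in the other Grow tumours. Glycolysis genes averaged 5.83 in Grow 5 against 5.31 to 5.46, and the imprinted gene network 3.142 in Regress 4 against 0.49 to 0.83. The cell death gene Bmf was lowest in Normal 2 (3.03 in log2 CPM against 4.55 to 4.60) and in Regress 3 (1.38 against 2.15 to 2.27), and the mitotic kinase Cdk1 in Grow 2 (1.69 against 2.56 to 2.99). Plekhb1 was at 4.99 in Normal 4 against 5.73 to 5.78 in the other normal livers. Dusp5 in Normal 3 (-1.19) and Erich4 in Normal 4 (-1.20) had counts where the other normal livers had none. Regress 3 had the smallest library, 4.71 M estimated counts against 5.96 to 6.17 M, and the length slope of Regress 4 was 0.40 log2 units per doubling against -0.49 to -0.39.

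Normal 2 with Regress 1, 2 and 3 differed from Normal 1, 3 and 4 with Regress 4 in 2192 genes, far more than the 3 genes called between Regress and Normal. The 1000 genes higher on the first side had a median transcript length of 1371 bases and the 1192 lower ones 4823, against 2859 over all tested genes. Counts taken by 28S ribosomal RNA and unnamed features are argued against as the cause, since 1843 genes were called without them, against 2041 of the same genes before. A difference between libraries in how counts depend on transcript length may account for most of the pattern, since 336 genes were called with each library's length trend removed, against 2015 of the same genes before. What set the length slopes is open, and no biological explanation was tested.

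Grow 3 and Grow 4 were nearly alike and held far more RNA of beta-catenin targets than the other libraries, with Axin2 at 61.4 and 57.1 CPM, Lgr5 at 15.3 and 17.7 CPM and Glul at 9962 and 9771 CPM. The imprinted transcripts Meg3 and Rian were also at 253 and 407 CPM in Grow 3, against at most 20.5 and 48.5 CPM in any library but these 2. A rise caused by SAHA with TMZ stays open: Glul in Grow 2, the only other library with this treatment, was at 159 CPM, below the highest normal liver at 583 CPM, and 1 library cannot settle it. A single tissue or RNA sequenced more than once may explain the likeness: the median squared difference of the 2 libraries was 1.504 times that of sampling noise, against 4.45 times in the closest other pair. The labels give them different codes, and pieces of 1 tumour or a shared origin of 2 tumours stay open.

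Regress 1 lay close to normal liver. Its median position over the genes that separate tumours from normal liver, with the length trend removed, was 0.102, where 0 is the normal mean and 1 the tumour mean, and the highest normal liver was at 0.338. TMZ bringing a tumour back to the normal profile stays open, since only Regress 3 had the same dose, and it lay at 0.979. A normal liver labelled as a tumour may explain this position. Ccnd1 (11.4 against 3.33 to 5.53 CPM in normal livers), Dusp6 (37.4 against 18.1 to 22.3 CPM) and Mpzl1 (6.50 against 0.727 to 1.79 CPM) lay above every normal liver. All 3 were also among the 667 genes called without Regress 1. They were named because they passed with Regress 1 in the fit as well, so they cannot weigh against that explanation. Among lists fixed beforehand, proliferation genes averaged 0.64 log2 CPM in Regress 1, above the -0.16 to 0.18 of normal livers. Oncofetal markers averaged 0.30, within the normal range of 0.001 to 0.78. A piece that mixed normal liver with some tumour tissue stays open.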

How the results depend on the processing

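Corrections for transcript length and GC content, the summing of Grow 3 and Grow 4, the division by the value of 1 read, the clock covariate, the fits on named genes or on single transcripts and the fit without Regress 1, Normal 2 and Grow 4 were chosen only after the data were seen. The 55 named gene results that passed the threshold kept their direction under all settings run. Under settings other than leaving out 1 library, 896 of their values stayed past the threshold and 228 did not, and with 1 library left out 843 did and 457 did not. Of the 26 that had not passed, 420 and 432 values kept their side, 54 and 31 passed, and 32 and 33 reversed. Ccnd1 in Tumour vs Normal passed in 45 of 48 settings (2.86 to 3.38), and in Regress vs Normal Ccnd1 passed in 23, Dusp6 in 21 and Mpzl1 in 21 of 37. Of the 80 list calls by camera, 344 values kept, 267 lost and 2 reversed their call under other settings, and 680 kept, 90 lost and 2 reversed it with 1 library left out. A main limit is the 4 normal livers, whose removal in turn moved every count of tumours against normal liver. At these library totals (4.71 to 13.39 M estimated counts) and this spread, edgeR recovered 4.55% of genes changed by 1 on the log2 scale in simulated Regress vs Normal data, and depth was not varied. Replicate numbers did not pair the samples: 2 of 12 same-numbered pairs had deviations that correlated above 0.1, from -0.52 to 0.20, and 2 of 24 checks found a sample closest to its own number. With a replicate block edgeR called 0, 0, 0 and 0 genes in the 4 group comparisons (1312, 1076, 1098 and 331 at an unadjusted p under 0.05). The fit on only the groups compared equals the main one for Tumour vs Normal and gives no separate value. Where a result changed, the cause was not tested.

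Counts of called genes are given for Tumour, Grow and Regress vs Normal, in this order, mainly where they moved by more than 1.5 times. DESeq2 called 1055, 1014 and 712, and 31 in Regress vs Grow, 464 for TMZ and 52 for SAHA. limma-voom called 127 (45 higher, 82 lower), 90 (32 higher, 58 lower) and 0, and 2 for TMZ. RLE factors gave 35 and upper-quartile factors 0 in Regress vs Normal. Without a filter the count was 214 (200 of them among the 285), 165 (152 among the 217) and 2, and 1 for TMZ. Without robust estimates it was 23 in Regress vs Normal. Only the groups compared gave 877 for Grow and 0 for Regress. SAHA and TMZ as covariates gave 876, 319 and 445, with 262, 116 and 3 of them among the 285, 217 and 3, and vehicle-treated tumours only 941, 488 and 511, with 226, 116 and 3. Without both samples of the shared code it was 0, 18 and 0 (1493 and 1175 genes at an unadjusted p under 0.05 for Tumour and Regress). Grow 3 and Grow 4 summed gave 216, 113 and 0, leaving out 3 libraries 613, 213 and 397, division by the value of 1 read 50 in Regress, named genes without Rn28s1 76 in Regress and 1 for TMZ, and the clock covariate 326, 79 and 569. With the length trend removed the counts were 646, 529 and 184, and 71 for TMZ. Length and GC trends removed gave 780, 692 and 304, and 85 for TMZ. The length slope as a covariate gave 1060, 720 and 194, and 1 in Regress vs Grow. With the length trend removed and the 2 libraries summed the counts were 589, 468 and 171, and single transcripts gave 62, 28 and 5, and 1 in Regress vs Grow.

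Leaving out 1 library, with and without the length trend, the count ranged from 0 to 1425 in Tumour vs Normal, 4 to 498 in Grow vs Normal, 0 to 1086 in Regress vs Normal, 0 to 1249 in Regress vs Grow, 0 to 970 for TMZ and 0 to 1 for SAHA. With the length trend removed, Tumour vs Normal had 58, 185, 24 and 61 calls without Normal 1, 2, 3 and 4, 356 without Grow 6, 391 without Regress 3 and 1425 without Regress 1. Grow vs Normal had 76, 187, 39 and 82 without Normal 1 to 4 and 193, 250 and 187 without Grow 1, 5 and 6. Regress vs Normal had 0, 6, 0 and 5 without Normal 1 to 4 and 1086, 13, 4 and 37 without Regress 1 to 4. Regress vs Grow had 6, 7 and 311 without Regress 1, 2 and 4. TMZ had 970, 9, 12 and 196 without Grow 2, Grow 5, Regress 1 and Regress 3 and none by edgeR without Grow 1, 3, 4, 6 or Regress 2, and SAHA had 1 without Grow 1. Over these fits the log2 fold change ranged from -0.32 to 0.48 for Mgmt in Tumour vs Normal, -0.78 to 0.025 for Mgmt in Grow vs Normal, -1.44 to 0.88 for Glul in Regress vs Normal, -0.50 to 1.32 for Afp in Regress vs Grow, -2.04 to 0.37 for Gpc3 in Regress vs Grow and -0.63 to 0.84 for Cdkn1a in Regress vs Grow. It ranged from -1.35 to 0.037 for Cdkn1a in SAHA vs no SAHA in Grow tumours, -0.079 to 1.09 for Mgmt in SAHA vs no SAHA in Grow tumours and -0.46 to 0.32 for Mki67 in SAHA vs no SAHA in Grow tumours.

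Reversals under other settings, none of a gene called by edgeR, are given as log2 fold changes. Glul in Tumour vs Normal was at -0.56 with limma-voom, -1.33 with SAHA and TMZ as covariates and -1.04 with vehicle-treated tumours only, and Glul in Grow vs Normal at -0.16, -3.145 and -3.142 in the same order. Glul in Regress vs Normal was at -0.95 with limma-voom, -0.94 with the replicate block and -0.50 with the clock covariate, and Glul in Regress vs Grow at 3.63 with both drugs as covariates and 4.201 with vehicle-treated tumours only. Gpc3 in Regress vs Grow was at 0.63 with the replicate block, 0.27 with both drugs as covariates, 0.096 with vehicle-treated tumours only and 0.34 with the length slope as a covariate. Afp in Regress vs Grow was at -0.88 with limma-voom, and Mki67 in Regress vs Grow at 0.0019 with vehicle-treated tumours only. Mgmt in Tumour vs Normal was at 0.060 with limma-voom, 0.091 with the replicate block, 0.25 without the 3 libraries and 0.59 with the clock covariate. Mgmt in Grow vs Normal was at 0.16 and Mki67 in Regress vs Normal at -0.28 with the clock covariate. Mgmt in Regress vs Normal was at -0.10 with vehicle-treated tumours only and -0.098 with the length slope, and Mgmt in TMZ vs no TMZ in tumours at -0.053 with the length slope. Mki67 in SAHA vs no SAHA in Grow tumours was at 0.76 in tumours without TMZ, 0.15 with Grow 3 and Grow 4 summed, 0.066 with the length trend removed, 0.080 with length and GC trends removed, 0.43 with the length slope and 0.18 with the length trend removed and the 2 summed. Camera turned the lists of periportal genes (adjusted p = 0.160) and acute phase (0.973) in Regress vs Grow with vehicle-treated tumours only. With 1 library left out it turned p53 targets in SAHA vs no SAHA in Grow tumours (adjusted p from 3.71e-09 without Grow 5 to 0.789, turned, without Grow 1). It also turned lipogenesis in SAHA vs no SAHA in Grow tumours (from 6.33e-09 without Grow 1 to 0.455, turned, without Grow 5).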

Other observations

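The genes in this part were chosen after their values were seen, and the counts over other splits of the samples were chosen only after the result was seen. Some single genes rose in tumours in the comparison with normal liver. The fatty acid transporter Cd36 (log2 fold change 2.55 ± 0.41 SE, edgeR adjusted p = 0.0173) stood at 7.47 to 30.1 CPM in normal livers and at 45.3 to 168 CPM in all 10 tumours. Lipoprotein lipase (Lpl, 3.32 ± 0.66, adjusted p = 0.0290), the fatty acid binding protein Fabp4 (3.08 ± 0.61, adjusted p = 0.0290), the lipid droplet protein Cidec (4.25 ± 1.00, adjusted p = 0.0417) and the apolipoprotein Apoa4 (4.72 ± 1.09, adjusted p = 0.0397) rose as well, and Apoa4 reached 30969 CPM in Regress 2 against at most 612 CPM in normal liver. Of the serine synthesis enzymes, Phgdh (5.52 ± 1.13, adjusted p = 0.0291) went from 0.175 to 0.527 CPM in normal livers to 3.79 to 42.0 CPM in 9 tumours and 0.394 CPM in Regress 1, and Psat1 (4.25 ± 0.73, adjusted p = 0.0213) from 0.299 to 0.702 CPM to 1.97 to 27.5 CPM in all 10.

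Among core clock genes, the activator Arntl was at 0.436 to 2.39 CPM in the 4 normal livers and at 3.91 to 27.8 CPM in 9 tumours, with 0.395 CPM in Regress 2 (3.50 ± 0.89, edgeR adjusted p = 0.0539). The output gene Dbp was at 59.6 to 132 CPM in normal livers, 166 CPM in Regress 2 and 1.98 to 48.6 CPM in the other tumours (-1.72 ± 0.90, adjusted p = 0.346), so neither gene passed. Cry2 (-1.26 ± 0.28, adjusted p = 0.0356) was called lower, beside Per2, Hlf, Usp2 and Noct. The time of tissue collection is not in the labels used here, so a difference in time and a difference in the clock cannot be separated. Regress 2, which shares a code with Normal 4, thus lay near the normal livers in both genes, while the deviations of these 2 libraries from their group means correlated at 0.107 across genes, which are not independent replicates.

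Normal 2 differed from the other normal livers in sex-biased genes, although the Y-linked gene Ddx3y was at 86.0 CPM. The male-biased urinary protein gene Mup1, of a family with near-identical members, was at 36.3 CPM against 3907 to 32415, and Elovl3 had no count against 40.2 to 54.3 CPM. The female-biased gene Cyp3a44 was at 305 CPM, against at most 6.55 CPM in the other normal livers. Regress 4 held the most matrix RNA of all libraries, with Col1a1 at 186 CPM, Col3a1 at 266 CPM, Lum at 64.8 CPM and the macrophage glycoprotein Gpnmb at 217 CPM, against at most 9.59, 59.0, 20.1 and 16.2 CPM elsewhere.

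Whether the counts of called genes exceed those of other splits of the same samples was tested with edgeR on 100 splits, or on all where there were fewer. For Tumour against Normal 1 of the 100 splits drawn, the real one, reached 285 genes, and the highest other value was 252. For Grow against Normal 1 of the 100 drawn, the real one, reached 217, and the highest other value was 0. Chance thus gave as many genes in fewer than 5 of 100 splits drawn, which holds only if the samples are separate. That is open for Grow 3 and Grow 4 and for Normal 4 and Regress 2, and splits that were not drawn could call more. With Grow 3 and Grow 4 summed, 3 of 100 splits reached the 216 genes of Tumour against Normal, and the highest other split, Normal 2 with Regress 1 to 3 in place of the normal livers, called 3634. Chance thus gave as many genes in fewer than 5 of 100 splits, but the samples have a structure that can call more genes than the groups. For Grow against Normal 1 of 100 splits, the real one, reached the 113 genes with the 2 libraries summed, and 1 of all 84, the real one, reached the 18 genes without the samples of the shared code, with 1 and 5 as the highest other values. The first fit kept Normal 4 and Regress 2, and the second kept Grow 3 and Grow 4 as 2 samples. These counts too weigh against chance only if the samples kept are separate. Tumour against Normal had 0 genes by edgeR without these samples (1493 at an unadjusted p under 0.05) and could not be tested in this way. For Regress against Normal 3 of 35 splits reached 3 genes, and the highest other split called 2192, so chance cannot be excluded and the samples have a structure that the groups do not follow. For Regress against Grow 100 of 100 splits and for TMZ 60 of 60 reached the real edgeR count of 0, as any split must, so chance cannot be tested there this way. The highest other values were 1605 and 5 genes. SAHA, with 4 tumours against 2, was not tested in this way, and neither were the counts with the length trend removed.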
